A study of Mus musculus with 6 samples.

How the data were processed

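Bulk RNA sequencing measured messenger RNA in liver tissue of BALB/c mice with carbon tetrachloride (CCl4) fibrosis. Per the labels, tissue came from each liver lobe. Fresh frozen pieces gave total RNA, polyadenylated RNA was selected, libraries were made with a strand-marking TruSeq kit, and they were read in paired ends on a NovaSeq instrument. The comparison used 6 libraries, 3 from mice given alendronate-loaded nanoparticles (AL/NP) and 3 from fibrotic controls labelled untreated. The labels number the replicates without stating outright that each is a separate animal, and replicates were taken as such. They give no sequencing batch, cage or date.

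The deposited table held whole-number read counts per Ensembl gene identifier, with 1 column per library and no normalization, as the values themselves showed. Per the submitters' processing notes, the authors used the GRCm38 genome build, STAR 2.6.1a, featureCounts (no version given) and DESeq2 1.26.0. The notes give no strand setting, annotation release, treatment of reads with several matches, or filter. Because the strand setting is unknown, overlapping genes on opposite strands may share reads. All 6 columns matched 1 sample each by name. Of 41388 identifiers, 40254 had a gene symbol in the reference table and 1134 had none; 29551 had at least 1 count. Coordinates and gene types were taken from the GENCODE M21 annotation of GRCm38 by Ensembl identifier.

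Library totals ranged from 30554483 to 39838428 counts. A level of 3 counts corresponded to between 0.0826 and 0.104 CPM, the usual library-scaled count, which covers counting error only, since PCR copies are not independent molecules. Pairs of libraries were checked for duplicates with a chi-square statistic over genes with at least 10 counts in the pair, and no pair was closer than 30.6 per degree of freedom. Nuclear copies of mitochondrial genes were found with blastn 2.17.0 as annotated nuclear transcripts matching a mitochondrial gene at 95% identity or more over at least 100 bases and at least 50% of their length; there were 11.

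Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust dispersion and robust fit, TMM scaling, filterByExpr with its minimum count of 10), which left 15939 genes. P-values were adjusted by Benjamini-Hochberg over those genes, with a threshold of 0.05. Fold changes are log2 of AL/NP over control, CPM values are TMM-scaled, and SE is the absolute log2 fold change divided by the square root of the F statistic. Gene lists were compared with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 47 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. The 47 lists held 1112 genes and covered fibrosis, macrophages, inflammation, liver function, metabolism, the mevalonate pathway, stress, proliferation, other cell types and technical signs. List levels per library are the mean over members of log2 CPM minus the control mean.

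The lists, the tests of genes and lists between the groups, a set of 20 genes to report whatever their values, the rule for naming genes and all alternatives but 1 were fixed before the data were examined. Some tests of explanations, named in the last section, were chosen later. The rule named the 10 called genes with the largest rises and the 10 with the largest falls among those with at least 1 CPM and no overlap between groups, filled to 5 in a direction with the smallest p-values where fewer were called. It added the 20 set genes, the 3 members with the smallest p-value of each called list, and 1 such member of each list on fibrosis or macrophages that was not called. Predicted genes and identifiers without a symbol were passed over for the largest changes; none was called. Values of 2 genes that the rule chose are not reported here.

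The alternatives were DESeq2 size factors, library totals without scaling, no filter beyond 1 count, a filter of at least 50 counts in 3 libraries, the replicate number as a block, each library left out in turn, the fit without robust estimation, the 10 most abundant genes left out, limma-voom, and DESeq2 1.42.0 with default filtering. Leaving out mitochondrially encoded genes and their nuclear copies was added after the data were seen, as were 3 further gene lists, made before their own values were computed. On simulated data drawn from the means and library sizes of this comparison (15775 genes in the fit), the edgeR test recovered 54% of 100 genes changed 2-fold and 94.9% of 99 changed 4-fold, with 15 false calls among 163. DESeq2 recovered 70% and 96.0%, with 41 false calls among 206. A simulated list of 30 genes changed 1.5-fold was called, and 1 of 47 unchanged lists was called. Simulated genes were drawn independently, without inter-gene correlation, so this does not give the rate of false list calls in the real data.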

Results

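Liver RNA was compared between mice with CCl4 fibrosis that received AL/NP, nanogels carrying the bisphosphonate alendronate, and fibrotic mice without treatment. CCl4, a liver toxin, was given for 5 weeks. Per the labels, AL/NP was injected 2 times per week during the last 2 weeks, at 4 mg/kg alendronate. The title of the series asks whether such particles move liver macrophages out of an immunosuppressive state and act against fibrosis. Each group had 3 libraries. No healthy liver and no nanogel without drug was part of the samples, so the comparison does not separate the drug from its carrier. The labels do not say whether controls were injected, so it does not separate either from the injections. The AL/NP libraries held 30740173, 33283147 and 30554483 counts in replicates 1 to 3, and the control libraries held 32694163, 36064739 and 39838428. Between 22512 and 23394 genes had counts in each library.

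The first principal component of log2 CPM took 45.7% of the variance and the second 23.8%. All 3 AL/NP libraries lay on one side of the first component and all 3 controls on the other. AL/NP replicate 1, at -53.0, and control replicate 3, at 57.9, lay at its ends. Control replicate 3 also had the lowest TMM factor, 0.809, against 0.937 to 1.13 in the other 5 libraries. Mitochondrially encoded genes took 26.7% of its counts, against 16.2% and 19.8% in the other controls and 17.0%, 14.2% and 11.96% in AL/NP replicates 1 to 3. Nuclear copies of mitochondrial genes took a further 6.50% to 14.6% of counts per library. Over the 6 libraries Gm28661 had 3907482 counts and mt-Co2 had 3904291, and Gm28437 had 3892245 and mt-Co3 had 3888230, so reads that match both places seem to have been counted at both. The other 9 copies had between 0.00263 and 1.22 times the counts of their closest mitochondrial gene. Counts of all these genes are uncertain. Gm42418, a predicted gene chosen after its values were seen, took 1.04% of counts in AL/NP replicate 1 and 0.190% to 0.249% in the other 5.

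**Figure D1:**
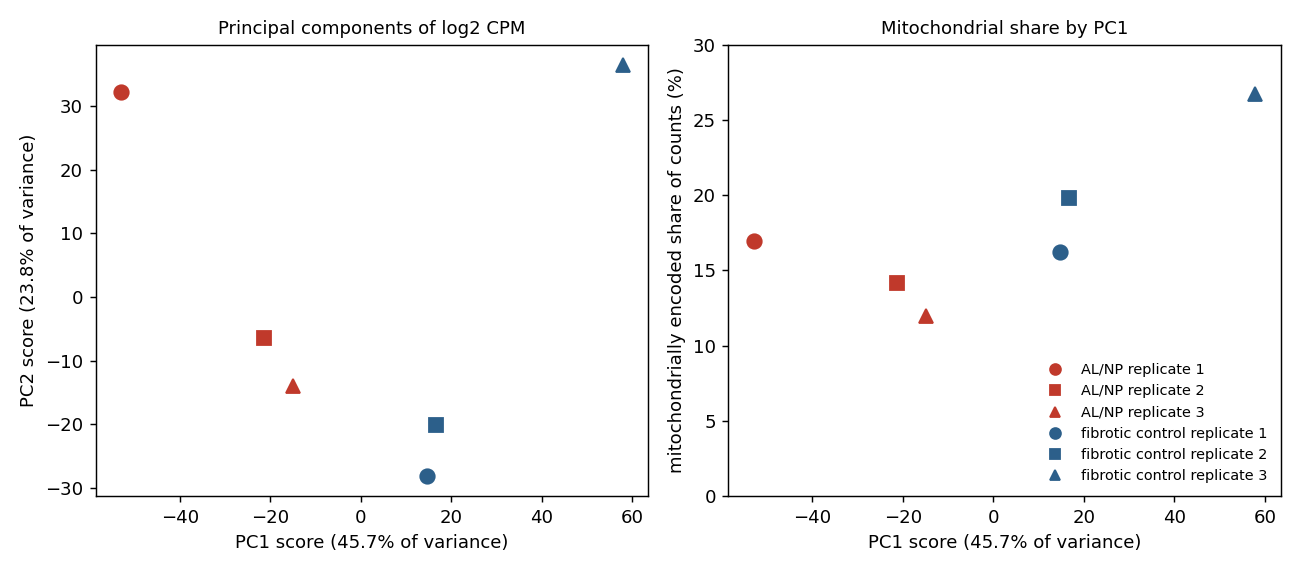
Left, the 6 libraries on the first and second principal components of log2 CPM (45.7% and 23.8% of variance). Right, the percent of counts from mitochondrially encoded genes against the first component; control replicate 3, at 26.7%, is the highest.

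The edgeR quasi-likelihood test called 13 of 15939 genes at an adjusted p of 0.05, 10 higher with AL/NP and 3 lower. All 13 adjusted p-values lay between 0.0480 and 0.0493, so the calls sat close to the threshold. At an unadjusted p under 0.05 there were 3128 genes (1494 higher, 1634 lower), against 797 expected by chance. At an adjusted p under 0.1 there were 142 genes, 88 higher and 54 lower. DESeq2 called 844 genes, 431 higher and 413 lower, and these included all 13. The groups did not overlap in 4698 genes, 29.5% of those tested, where chance gives 10%. The biological coefficient of variation was 23.3%. The edgeR count fell whichever library was left out, in fits with fewer samples, so this does not single out a library. It was 3 genes without AL/NP replicate 1, 4 without control replicate 1, and 0 without any one of AL/NP replicates 2 and 3 and control replicates 2 and 3. With those 4 libraries left out in turn, the unadjusted count was 2328, 2880, 2461 and 3022. DESeq2 was not run with libraries left out.

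The 10 genes called higher did not overlap between the groups. Saa1 (chromosome 7, 46740497 to 46742980, protein coding) rose most, by 4.15 on the log2 scale (SE 0.499, adjusted p = 0.0493, edgeR), from 51.3 ± 15.0 CPM (SD, n = 3) in controls to 909.5 ± 490.3 CPM with AL/NP. Saa3 (chromosome 7, 46711998 to 46715700) rose by 3.29 (SE 0.402), from 6.06 ± 1.78 to 59.1 ± 31.8 CPM. Hspa1b (chromosome 17, 34956436 to 34959238) rose by 2.43 (SE 0.232), from 9.72 ± 3.06 to 52.5 ± 6.51 CPM, and had the lowest adjusted p, 0.0480. Hspa1a (chromosome 17, 34969190 to 34972156) rose by 2.27 (SE 0.3001), from 3.99 ± 1.94 to 19.3 ± 1.20 CPM. Orm2 (chromosome 4, 63362449 to 63365878) rose by 1.78 (SE 0.236) and Orm3 (chromosome 4, 63356162 to 63359511) by 1.57 (SE 0.187). Saa1, Hspa1a, Hspa1b, Orm2 and Orm3 each have a near-identical relative, so the split of reads between relatives is uncertain. Metrnl (chromosome 11, 121701544 to 121716306) rose by 1.18 (SE 0.155), from 5.68 ± 0.310 to 12.9 ± 0.952 CPM.

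The other called rises were genes of cholesterol synthesis. Idi1 (chromosome 13, 8885501 to 8892451) rose by 1.79 (SE 0.224), from 36.3 ± 7.70 CPM (SD, n = 3) in controls to 125 ± 27.9 CPM with AL/NP. Cyp51 (chromosome 5, 4081145 to 4104746) rose by 1.68 (SE 0.209), from 46.9 ± 11.5 to 150.2 ± 14.1 CPM. Akap9 overlaps Cyp51 on the opposite strand and had 21.6 counts per 100 of Cyp51. Msmo1 (chromosome 8, 64718139 to 64733792) rose by 1.60 (SE 0.189), from 43.4 ± 9.46 to 132 ± 13.2 CPM. The adjusted p from edgeR was 0.0493 for all 3.

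Among the genes called lower, Dtl (chromosome 1, 191537356 to 191575544) fell by 2.47 on the log2 scale (SE 0.293), from 4.75 ± 0.2497 CPM (SD, n = 3) in controls to 0.846 ± 0.275 CPM with AL/NP. Ccdc141 (chromosome 2, 77009902 to 77170636) fell by 1.2596 (SE 0.164), from 19.3 ± 3.06 to 8.07 ± 0.515 CPM. The adjusted p from edgeR was 0.0493 for both. The next genes in that direction, Abcc4 (log2 fold change -1.24, SE 0.1702) and Timeless (log2 fold change -1.28, SE 0.178), did not pass, at an adjusted p of 0.0579.

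**Figure D2:**
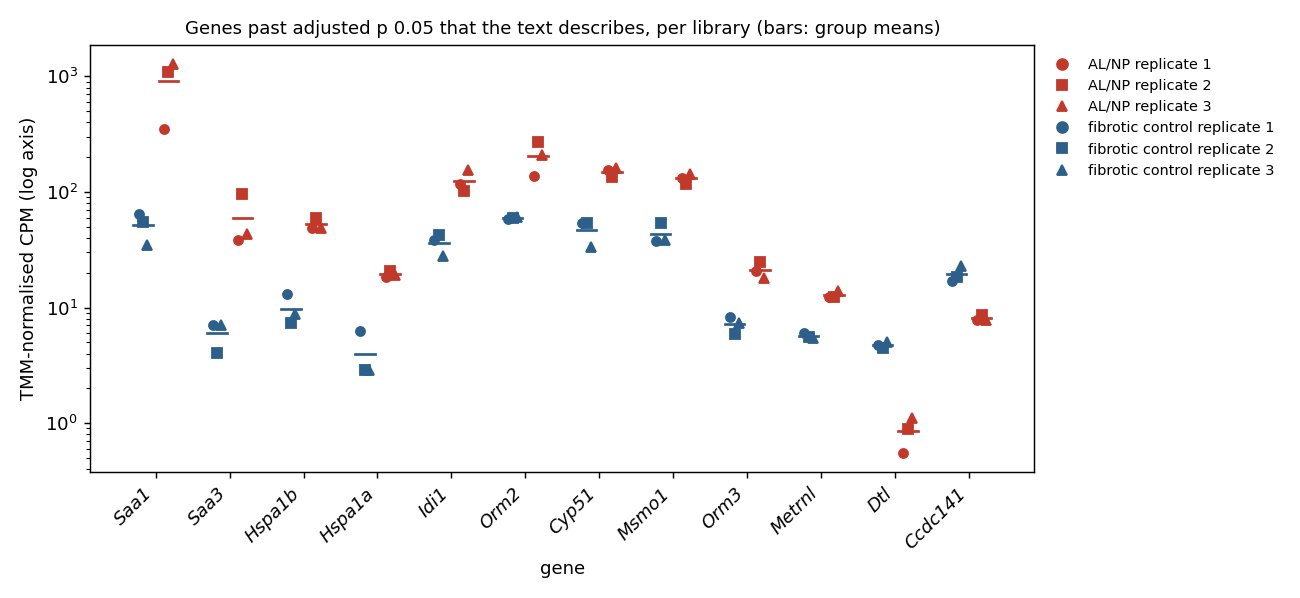
TMM-scaled CPM on a log axis for 12 of the 13 called genes in each library; horizontal bars are group means. In every gene shown the 3 AL/NP libraries lie apart from the 3 controls.

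Of the 20 genes set for reporting, 18 were tested and edgeR called 0 over all genes; 8 had an unadjusted p under 0.05 and DESeq2 called 3. Adjusted over the list alone, 3 passed. These were Il1b (log2 fold change 1.56, SE 0.271; 0.00534 over the list alone and 0.0839 over all genes), Fdps (1.11, SE 0.212; 0.00534 and 0.0954) and Tgfb1 (0.805, SE 0.212; 0.0266 and 0.140). None of the other tested genes passed either way. The groups did not overlap in these 3 genes, nor in Timp1, Cd68, Arg1 and Cd163, whose adjusted p over the list alone was 0.0517 to 0.0636. Among fibrosis genes, the log2 fold change was -0.680 for Col1a1 (SE 0.604), -0.679 for Col1a2 (SE 0.547), -0.411 for Col3a1 (SE 0.488), -0.484 for Acta2 (SE 0.385), -0.159 for Pdgfrb (SE 0.206), 0.157 for Mmp13 (SE 0.391) and 0.872 for Timp1 (SE 0.301). Col1a1 measured 219 CPM in control replicate 3, 51.7 and 86.2 in the other controls, and 38.6, 57.2 and 127 with AL/NP. Without control replicate 3 the log2 fold changes were 0.102 for Col1a1, 0.0661 for Col1a2, 0.116 for Col3a1 and 0.00329 for Pdgfrb. Without control replicate 2 that of Mmp13 was -0.152. That of Acta2 was -0.965 without AL/NP replicate 3 and -0.186 without AL/NP replicate 1. With library totals as the only scaling, Pdgfrb was at 0.0104 where the median of all genes was at 0.133.

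Among macrophage genes of the same set, the log2 fold change was 1.11 for Adgre1 (SE 0.396), 0.449 for Cd68 (SE 0.148), -0.203 for Clec4f (SE 0.344), 0.126 for Mrc1 (SE 0.228), -0.469 for Arg1 (SE 0.179), -1.28 for Cd163 (SE 0.410) and 1.11 for Tnf (SE 0.507). Adgre1 measured 8.01 CPM in AL/NP replicate 3 and 3.09 and 4.16 in the other AL/NP libraries, and its log2 fold change was 0.619 without AL/NP replicate 3. Clec4f was at 0.259 without control replicate 3, and at 0.0178 with library totals as the only scaling, where the median of all genes was at 0.133. Mrc1 was at -0.0984 without AL/NP replicate 3 and at -0.0445 without control replicate 3. Arg1 measured 861 CPM with AL/NP and 1192 CPM in controls, far above Mrc1 at 19.9 and 18.3 CPM. Bulk liver RNA does not show which cells carried Arg1, so its fall cannot be read as one in macrophages. Nos2 and Il10 were too low to test. Nos2 had 18 counts over the 3 AL/NP libraries and 4 over the 3 controls, and Il10 had 2 and 6, so no difference in Il10 was detectable at this depth.

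Camera with the preset correlation called 21 of 47 lists, 16 higher with AL/NP and 5 lower. With an estimated correlation it called 0; the unadjusted p was under 0.05 in 23 lists with the preset correlation and in 7 with the estimated one. Fry, which asks whether the members of a list move on balance one way, called 1, the acute phase genes, with 14 at an unadjusted p under 0.05, and 31 lists passed its test of change in either direction. Median, mean and test differed in sign in 3 lists, those of ribosomal protein genes, mesothelial markers and adipocyte markers, and none of these was called. Several called lists shared genes, so their calls were not independent. Genes also in another list were 20 of 40 for cytochrome P450 enzymes, 17 of 31 for chemokines, 15 of 26 for M2-type genes and 9 of 22 for infiltrating monocytes. The mevalonate and cell cycle lists had 0. Other divisions of the 6 libraries into 3 and 3 called between 9 and 24 lists, so a count of called lists did not set the treatment apart from other differences among these libraries.

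**Figure D3:**
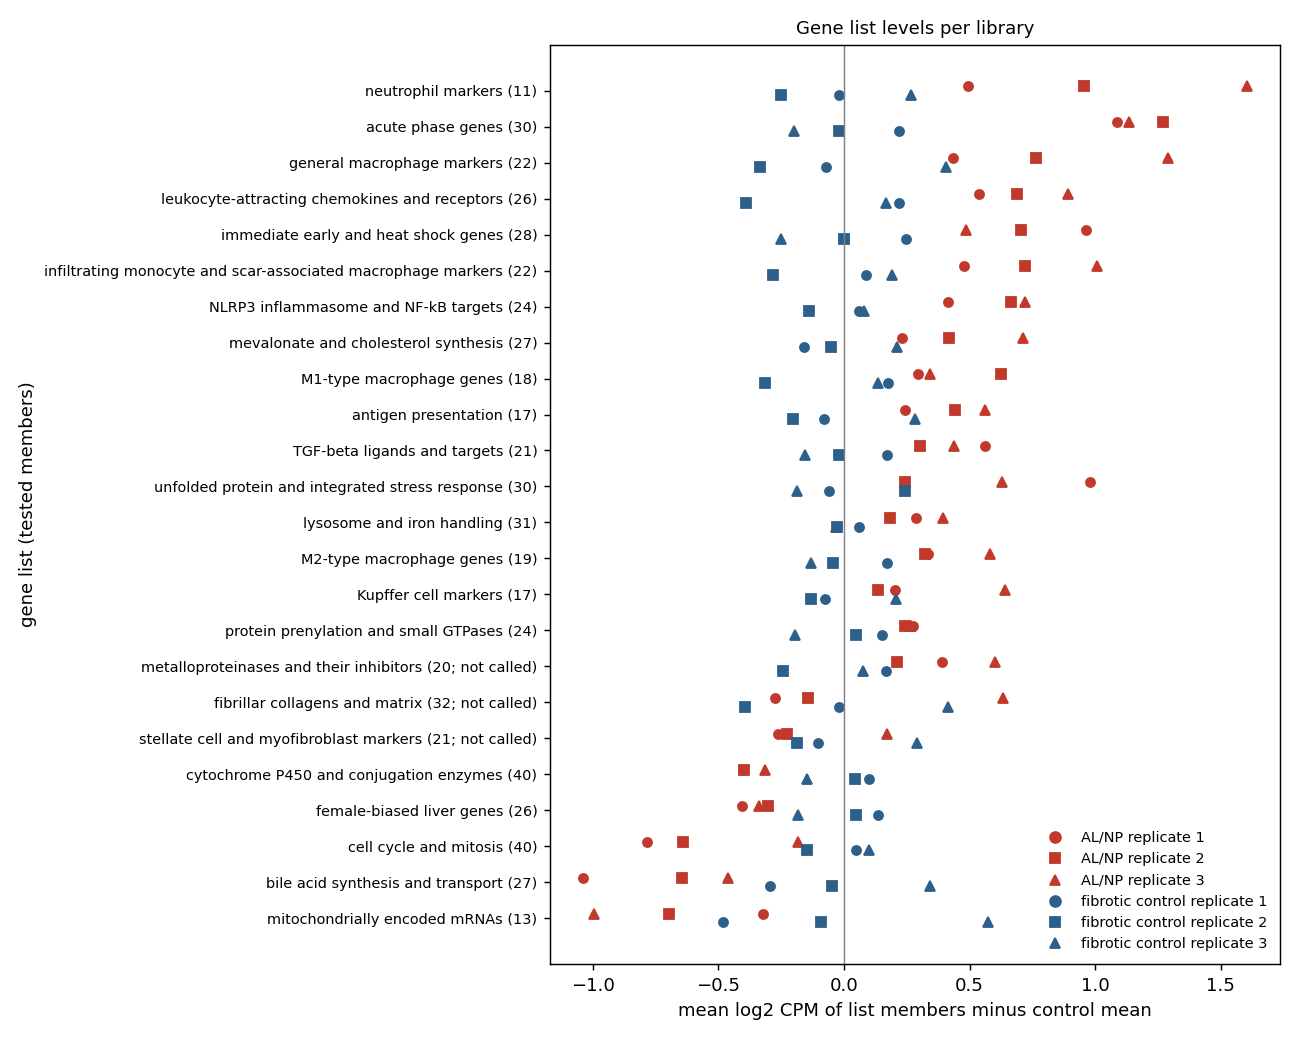
Mean log2 CPM of list members minus the control mean in each library, for called lists and for lists on fibrosis and macrophages that were not called; tested members are in brackets. For acute phase genes the AL/NP libraries lie between 1.09 and 1.27 and the controls between -0.200 and 0.221, whereas for fibrillar collagens and matrix the groups overlap.

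Acute phase genes had a median log2 fold change of 0.971, with 28 of 30 tested members higher (camera adjusted p = 2.52e-25; adjusted p = 0.111 with an estimated correlation; fry adjusted p = 0.0169). Their level relative to controls was 1.16 ± 0.0956 (SD, n = 3) with AL/NP, and the SD of controls was 0.211. In this list 4 members were called over all genes and 16 adjusted over the list alone, all higher; the smallest p-values were those of Orm3, Saa1 and Saa3. Immediate early and heat shock genes, a list kept as a sign of handling or stress, had a median of 0.761 with 24 of 28 higher (camera adjusted p = 2.54e-10; adjusted p = 0.230 with an estimated correlation). Its leading members were Hspa1b, Hspa1a and Ccn1, the last at 1.27 (SE 0.182, adjusted p = 0.0617). Genes of the NLRP3 inflammasome and NF-kB targets had a median of 0.566 with 21 of 24 higher (camera adjusted p = 1.82e-07; adjusted p = 0.313 with an estimated correlation). They were led by Icam1 at 0.776 (SE 0.133), Il1b, and Ccl3 at 1.93 (SE 0.391), with adjusted p of 0.0787, 0.0839 and 0.0998. The unfolded protein and integrated stress response list had a median of 0.386 with 29 of 30 higher (camera adjusted p = 7.61e-06; adjusted p = 0.402 with an estimated correlation), led by Dnajb9 at 1.34 (adjusted p = 0.103), Fgf21 at 4.39 and Chac1 at 2.47 (adjusted p = 0.144 for both). Fgf21 rested largely on AL/NP replicate 1, with 162 CPM against 12.6 and 18.5 in the other AL/NP libraries and 1.18 to 5.36 in controls; without AL/NP replicate 1 its log2 fold change was 2.34. The same held for Chac1, with 13.9 CPM in AL/NP replicate 1 against 2.48 and 3.25 in the other AL/NP libraries; without AL/NP replicate 1 it was at 1.29.

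General macrophage markers had a median log2 fold change of 0.961 with 21 of 22 higher (camera adjusted p = 1.16e-08; adjusted p = 0.400 with an estimated correlation). Without AL/NP replicate 3 the median was 0.571. None of the 22 passed over all genes, whereas 12 passed as higher and 1 as lower adjusted over the list alone, and DESeq2 called 5 higher and 1 lower. The smallest p-values were those of Mpeg1 at 1.20 (SE 0.166, adjusted p = 0.0579), Laptm5 at 1.44 (SE 0.278, adjusted p = 0.0970) and Lgals3, which went the other way at -0.583 (SE 0.139, adjusted p = 0.124). Neutrophil markers had a median of 1.25 with all 11 tested members higher (camera adjusted p = 7.60e-07; adjusted p = 0.355 with an estimated correlation), led by Lcn2 at 1.63, S100a9 at 1.30 and Trem1 at 2.08. Lcn2 was also a member of the acute phase list, and 4 of the 20 genes of the neutrophil list were in another list. The neutrophil level was 0.492 and 0.955 in AL/NP replicates 1 and 2 and 1.61 in AL/NP replicate 3. Leukocyte-attracting chemokines and receptors had a median of 0.839 with 22 of 26 higher (camera adjusted p = 7.60e-07; adjusted p = 0.341 with an estimated correlation), led by Ccl6 at 1.63, Ccl3, and Cxcl1 at 1.34. Markers of infiltrating monocytes and scar-associated macrophages had a median of 0.652 with 19 of 22 higher (camera adjusted p = 4.91e-06; adjusted p = 0.329 with an estimated correlation), led by Chil3 at 3.78, Ms4a4c at 1.43 and Itgam at 1.35. None of the leading genes of the last 3 lists passed over all genes, with adjusted p from 0.0783 to 0.132.

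The calls of the Kupffer, M1-type and M2-type lists were each lost under some alternatives. Kupffer cell markers, those of resident liver macrophages, had a median log2 fold change of 0.372 with 12 of 17 higher (camera adjusted p = 0.0118; adjusted p = 0.469 with an estimated correlation). That median was -0.0437 without AL/NP replicate 3, and the call was also lost without control replicate 1 (adjusted p = 0.0566) and without control replicate 2 (0.0618). Over 12 alternatives with the preset correlation its adjusted p ranged from 0.00112 to 0.126. Cd5l was at 1.264 (adjusted p = 0.0640) and Adgre4 at 1.45 (adjusted p = 0.108), whereas Cd163 was at -1.28 (adjusted p = 0.172). M1-type genes, linked to inflammatory macrophages, had a median of 0.460 with 12 of 18 higher (camera adjusted p = 0.0130; adjusted p = 0.402 with an estimated correlation). The M1 median was 0.1204 without AL/NP replicate 2 and 0.348 without control replicate 2, and neither was called (adjusted p = 0.0861 and 0.149); it was 0.721 without control replicate 1. Over the same alternatives the adjusted p of the M1 list ranged from 5.31e-04 to 0.149. Besides Il1b, Fpr2 at 1.52 (adjusted p = 0.123) and Irf5 at 0.949 (adjusted p = 0.149) led it, and Irf5 overlaps Tnpo3 on the opposite strand. M2-type genes, linked to macrophages of tissue repair, had a median of 0.377 with 13 of 19 higher (camera adjusted p = 0.0434; adjusted p = 0.400 with an estimated correlation). The M2 call was lost without AL/NP replicate 3 (adjusted p = 0.0913) and without control replicate 3 (0.263). It was also lost with library totals as the only scaling (median 0.485) and with at least 50 counts in 3 libraries (median 0.182, adjusted p = 0.419); the lowest adjusted p over the same alternatives was 0.00515. Klf4 at 1.62 (adjusted p = 0.0970), Chil3, and Clec10a at 1.60 (adjusted p = 0.128) led the M2 list. Its 6 lower members included Cd163, which alone of these passed adjusted over the list (adjusted p = 0.0488), Arg1, and Ccl24 at -0.868 (adjusted p = 0.230 over all genes). The level of Arg1 in whole liver cannot be assigned to macrophages. A difference between the M1 and M2 lists was not tested.

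Lysosome and iron handling genes had a median log2 fold change of 0.378 with 23 of 31 higher (camera adjusted p = 1.22e-04; adjusted p = 0.341 with an estimated correlation). That median was 0.243 without AL/NP replicate 3. The list was led by Npc2 at 1.02, Grn at 0.711 and Psap at 0.717, with adjusted p from 0.0783 to 0.108. Antigen presentation genes had a median of 0.406 with 13 of 17 higher (camera adjusted p = 0.00271; adjusted p = 0.469 with an estimated correlation). They were led by H2-Eb1 at 0.872, H2-D1 at 0.482 and H2-Ab1 at 0.817, with adjusted p from 0.135 to 0.184.

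Alendronate acts on farnesyl diphosphate synthase, the product of Fdps, in the mevalonate pathway, so genes of that pathway were compared. Mevalonate and cholesterol synthesis genes had a median log2 fold change of 0.498 with 19 of 27 higher (camera adjusted p = 1.47e-08; adjusted p = 0.355 with an estimated correlation). Their level relative to controls was 0.454 ± 0.244 (SD, n = 3) with AL/NP, and the SD of controls was 0.190. Without AL/NP replicate 3 the median was 0.383. Msmo1, Cyp51 and Idi1 passed over all genes, 14 members passed adjusted over the list alone, all higher, and DESeq2 called 10. Genes of protein prenylation and small GTPases, which use products of the pathway, had a median of 0.305 with 17 of 24 higher (camera adjusted p = 0.00511; adjusted p = 0.469 with an estimated correlation). Without control replicate 3 that median was 0.142. The list was led by Rap1b at 0.620, Rhob at 0.610 and Rhoc at 0.927, with adjusted p from 0.124 to 0.149. Fatty acid and triglyceride synthesis genes were not called, with a median of -0.0447 and 11 of 29 higher.

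For fibrosis, the list of fibrillar collagens and matrix was not called, with a median log2 fold change of 0.0929 and 17 of 32 higher (camera adjusted p = 0.498). The median was negative without AL/NP replicate 3 (-0.329), without control replicate 1 (-0.0385) and without control replicate 2 (-0.159). It was positive and called without AL/NP replicate 1 (0.273, adjusted p = 0.0368) and without control replicate 3 (0.328, adjusted p = 0.0237), so no direction was established; with an estimated correlation and all libraries the adjusted p was 0.963. Over 12 alternatives its adjusted p ranged from 0.0237 to 0.623. Thbs1 had its smallest p, at 1.01 (SE 0.357, adjusted p = 0.198). Stellate cell and myofibroblast markers had a median of -0.159 with 7 of 21 higher (camera adjusted p = 0.740), and of 0.0104 with library totals as the only scaling. That median was -0.325 without AL/NP replicate 3 and -0.0504 without AL/NP replicate 1. Ecm1 had the smallest p, at 0.489 (adjusted p = 0.202). Metalloproteinases and their inhibitors had a median of 0.251 with 13 of 20 higher (camera adjusted p = 0.0525; adjusted p = 0.560 with an estimated correlation). They were called without a filter on low counts (median 0.285), with the replicate block (median 0.265), and in 4 of the 6 fits that left out a library, without AL/NP replicates 1 and 2 and without control replicates 1 and 3 (adjusted p = 0.00861 to 0.0368, within 0.00861 to 0.332 over 12 alternatives). Their median was 0.0306 without control replicate 2 and 0.507 without control replicate 3. TGF-beta ligands and targets were called higher, with a median of 0.397 and 17 of 21 higher (camera adjusted p = 3.17e-04; adjusted p = 0.329 with an estimated correlation). Beside Ccn1, Tgfbi at 1.0025 (SE 0.192, adjusted p = 0.0962) and Ccn2 at 1.83 (SE 0.364, adjusted p = 0.0998) led it.

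Of the lists called lower, cell cycle and mitosis had a median log2 fold change of -0.524 with 8 of 40 higher (camera adjusted p = 2.30e-07; adjusted p = 0.400 with an estimated correlation). Its level relative to controls was -0.785, -0.640 and -0.182 in AL/NP replicates 1 to 3, and the controls lay between -0.148 and 0.101. Mcm3 at -0.876, Mcm6 at -0.979 and Cdk1 at -0.995 led it, with adjusted p from 0.108 to 0.128. Bile acid synthesis and transport genes had a median of -0.668 with 6 of 27 higher (camera adjusted p = 2.82e-07; adjusted p = 0.341 with an estimated correlation), and of -0.356 without control replicate 3. Beside Abcc4, Abcg5 at -1.82 (SE 0.280, adjusted p = 0.0749) and Abcg8 at -1.65 (SE 0.268, adjusted p = 0.0783) led it; these neighbours overlap on opposite strands, so their counts are not fully separate. Cytochrome P450 and conjugation enzymes had a median of -0.280 with 14 of 40 higher (camera adjusted p = 8.60e-04; adjusted p = 0.230 with an estimated correlation), and of -0.181 without AL/NP replicate 2. Cyp3a25 at -1.43 (adjusted p = 0.0903) and Cyp3a59 at -1.94 (adjusted p = 0.105) were among its members with the smallest p. Female-biased liver genes had a median of -0.325 with 9 of 26 higher (camera adjusted p = 8.60e-04; adjusted p = 0.230 with an estimated correlation). Hao2 at -1.51 (adjusted p = 0.0928) and Cyp2c40 at -0.553 (adjusted p = 0.126) were among its members with the smallest p, and 11 of its 28 genes were in another list. Mitochondrially encoded mRNAs had a median of -0.671 with 0 of 13 higher (camera adjusted p = 1.14e-05; adjusted p = 0.483 with an estimated correlation), and of -0.359 without control replicate 3. They were led by mt-Nd5 at -1.01, mt-Atp8 at -0.952 and mt-Nd4l at -0.864, with adjusted p from 0.134 to 0.204, and the last pair overlap mt-Atp6 and mt-Nd4. Without control replicate 3, mt-Nd4l was at -0.423.

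The remaining lists were not called, with camera adjusted p between 0.0710 and 0.948. The smallest were those of periportal hepatocyte genes (median -0.451, 10 of 26 higher) and dendritic cell markers (median 0.405, 11 of 18 higher, adjusted p = 0.105). Among lists of other cells, the median was 0.0312 for sinusoidal and vascular endothelial markers, 0.433 for cholangiocyte markers, 0.101 for T and NK cell markers, -0.0661 for B cell and plasma cell markers, -0.190 for hepatocyte secretory and core genes and -0.257 for pericentral hepatocyte genes. Interferon-stimulated genes had a median of 0.121, p53 targets 0.149, NRF2 and oxidative stress genes -0.00370, PPAR-alpha targets and fatty acid oxidation 0.0806 and circadian clock genes -0.0147.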

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

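The alternative that left out mitochondrially encoded genes and their nuclear copies was chosen after seeing the data; it gave 10 higher and 3 lower genes, the same 13. DESeq2 size factors also gave the same 13, and leaving out the 10 most abundant genes gave those 13 and 1 more.

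The number of genes past the threshold was otherwise not stable. With library totals as the only scaling 0 genes were higher and 0 lower (2254 at an unadjusted p under 0.05; smallest adjusted p 0.0596), and the median of all genes moved to 0.133. That scaling left Pdgfrb at 0.0104, Clec4f at 0.0178 and stellate cell and myofibroblast markers at 0.0104, all below that shift. Without a filter on low counts 374 were higher and 373 lower, among them 11 of the 13. With at least 50 counts in 3 libraries, where fewer genes were tested, 0 were higher and 0 lower (smallest adjusted p 0.0553; 2786 unadjusted). Without robust estimation 0 were higher and 0 lower (smallest 0.0513; 3133 unadjusted). Limma-voom gave 9 higher and 1 lower, and DESeq2 431 higher and 413 lower. The cause was not tested for these.

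With 1 library left out, which leaves fewer samples, between 0 and 3 genes were higher and between 0 and 2 lower. Lists called higher numbered 14 to 22 and lists called lower 5 to 7. Across these 6 fits log2 fold changes ran from -1.31 to 0.102 for Col1a1, -1.25 to 0.0661 for Col1a2, -0.996 to 0.116 for Col3a1, -0.337 to 0.00329 for Pdgfrb, -0.152 to 0.519 for Mmp13, -0.498 to 0.259 for Clec4f and -0.0984 to 0.261 for Mrc1. Medians ran from -0.0437 to 0.515 for Kupffer cell markers and from -0.329 to 0.328 for fibrillar collagens and matrix.

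An estimated inter-gene correlation ended all 21 calls among the 47 lists fixed beforehand, leaving 0 higher and 0 lower, and fry kept 1 higher and 0 lower. With every other alternative that was run on lists, 14 to 22 were higher and 4 to 7 lower.

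Replicate numbers showed no clear pairing: deviations of same-numbered libraries correlated at -0.0548, 0.0427 and 0.0752. AL/NP replicates 1 and 2 were each closer to another control number, whereas AL/NP replicate 3 was closest to control replicate 3. So few libraries per group cannot exclude a pairing. With the replicate block 14 genes were higher and 9 lower, 8 of them among the 13, and 17 lists were higher and 6 lower.

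For the 81 genes the rule chose, 835 values under an alternative kept their direction and side of the threshold, 106 kept the direction and no longer passed, 94 newly passed and 10 changed sign, in 7 genes. Most of the 835 were values of genes that were not called and stayed so. All 106 losses fell on the 13 called genes, which passed in only 3 (Saa3) to 6 (such as Hspa1b) of 13 alternatives each. For 24 lists the numbers were 266, 8, 8 and 5, in 3 lists. None of the genes or lists that changed sign was called except Kupffer cell markers. Depth limited genes near 0.1 CPM, such as Nos2 and Il10.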

Other observations

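Tests chosen only after the result was seen were those of the hepatocyte share, of lipid synthesis in general, and of single libraries (AL/NP replicate 3 and control replicate 3). The other tests were set before their results were seen. For the tests of the nuclear receptor LXR and of DNA replication, the limits written beforehand held no margin, and those applied asked for a value above its standard error. Without that margin the values, 0.114 and 0.0703, would have counted against both explanations.

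The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. By edgeR, 1 of the 10 divisions, the real one, gave as many genes as its 13, and the highest other gave 0. By DESeq2, 1 of the 10 gave as many as 844, and the highest other gave 21. For lists called by camera, 3 of the 10 gave at least the real 21, and the highest other gave 24. That highest value occurred both when AL/NP replicates 1 and 3 were grouped with control replicate 3 and when AL/NP replicate 1 was grouped with control replicates 1 and 2, so the libraries hold structure beside the treatment. Of the 21 called lists, 6 had their smallest p at the real division: acute phase genes (5.37e-27, smallest other 5.03e-08), immediate early and heat shock genes (1.08e-11 and 2.14e-09), NLRP3 inflammasome and NF-kB targets (1.93e-08 and 4.96e-06), bile acid synthesis and transport (4.20e-08 and 9.53e-08), lysosome and iron handling (3.39e-05 and 3.34e-04) and female-biased liver genes (2.93e-04 and 6.28e-04). General macrophage markers did not, with 7.39e-10 at the real division and 1.20e-23 at another. Neither did mevalonate and cholesterol synthesis (1.25e-09 and 1.92e-10), cell cycle and mitosis (2.94e-08 and 2.66e-11) or neutrophil markers (1.39e-07 and 4.84e-11).

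Lists of macrophage, neutrophil and chemokine genes were called higher with AL/NP at the preset correlation. With an estimated correlation none was called (adjusted p = 0.400 for general macrophage markers, 0.355 for neutrophil markers and 0.341 for chemokines). Control replicate 3 had the highest control level of general macrophage markers (0.406, against -0.0718 and -0.335 in control replicates 1 and 2). Leaving it out was therefore set to raise the median, which was 1.35 without it (0.961 with all libraries), and this was no test of other explanations. AL/NP replicate 3 stays open as a large part of the pattern: without it the median was 0.571, still called but lower. A smaller share of hepatocyte RNA would raise markers of every other cell type alike, which was examined after the list values were seen. The gap between general macrophage markers and stellate cell and myofibroblast markers was 0.935 wider with AL/NP (SD 0.215 among AL/NP libraries and 0.135 among controls), past the bound of 2 SD. The gap to B cell and plasma cell markers, 0.891 wider (SD 0.320 and 0.244), was also past it. The gaps to endothelial markers (0.770, SD 0.239 and 0.442), T and NK cell markers (0.530, SD 0.595 and 0.169) and cholangiocyte markers (0.672, SD 0.772 and 0.504) were not. The gap to fibrillar collagens and matrix was 0.758 wider (SD 0.134 and 0.0553), past the bound. Macrophage markers thus rose apart from stellate, B cell and collagen and matrix genes, and the other gaps decided nothing. For neutrophil markers the gap to stellate markers was 1.12 wider (SD 0.342 and 0.0769), past the bound. Their gaps to B cell, endothelial and collagen genes were also past it, whereas those to T and NK cell (0.718, SD 0.723 and 0.263) and cholangiocyte markers (0.860, SD 0.901 and 0.386) were not. Stellate cell and myofibroblast markers were themselves at a median of -0.159, B cell and plasma cell markers at -0.0661 and endothelial markers at 0.0312. These medians gave no sign of the rise that a smaller share of hepatocyte RNA would bring. Cholangiocyte markers were at 0.433 and hepatocyte secretory and core genes at -0.190, neither called, so such a share stays open as a part of the cause. A larger number of these cells, or more of these transcripts per cell, in response to AL/NP may also explain the lists; bulk RNA does not separate them, and no test of a biological explanation was made.

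Acute phase genes were higher with AL/NP in all 3 libraries. Removal of the trend on GC content and transcript length left the median at 0.932 (0.971 with all libraries and no correction). That trend was therefore not the whole cause. Control replicate 3 lay at -0.200, the other controls at 0.221 and -0.0210, and the AL/NP libraries between 1.09 and 1.27. Leaving it out could therefore move the median only a little, and the 0.911 without it was no further test. Leaving out mitochondrially encoded genes and their nuclear copies rescaled all other genes alike (median of all genes 0.0124). The median of 0.984 in that fit therefore decided nothing. The list stayed called by camera at the preset correlation in all 3 cases; with an estimated correlation and all libraries it was not called (adjusted p = 0.111). GC content and length explained 3.90% of the variance of fold changes. Reads shared between near-identical genes such as Saa1 and its relative remain open for those genes. Of 30 tested members 28 were higher and 2 lower. Outside the Saa and Orm genes, Lbp rose by 0.975 (SE 0.149), Hp by 1.30 (SE 0.234), Hpx by 1.10 (SE 0.213) and Apcs by 0.968 (SE 0.185). These values argue against shared reads of Saa and Orm genes as the whole cause. A difference in handling or stress of the animals or tissue also remains open. The labels give no dates, and the list kept as its sign, immediate early and heat shock genes, was also higher (median 0.761, 24 of 28 higher; adjusted p = 0.230 with an estimated correlation). A hepatic acute phase response to AL/NP may explain the pattern, as a hypothesis; drug, carrier and repeated injection cannot be separated in this design, since the labels do not say whether controls were injected.

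Mevalonate and cholesterol synthesis genes were called higher with AL/NP at the preset correlation and not with an estimated one (adjusted p = 0.355). After removal of the GC content and length trend the median was 0.502 (0.498 before), so that trend was not the whole cause. Control replicate 3 had the highest control level (0.210, against -0.160 and -0.0497), so the median of 0.560 without it decided nothing. AL/NP replicate 3 had the highest level (0.714, against 0.230 and 0.418 in AL/NP replicates 1 and 2), and without it the median was 0.383, still called at the preset correlation. Whether lipid synthesis genes rose in general was not settled. Fatty acid and triglyceride synthesis genes had a median of -0.0447, but members went both ways, with a spread (MAD) of 0.652 that exceeded the distance of 0.543 between the medians. A response of the pathway to inhibition of farnesyl diphosphate synthase by alendronate is a candidate explanation that was not tested.

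Abcg5 and Abcg8 were low with AL/NP without passing the threshold, and lower activity of the nuclear receptor LXR was tested as a cause on 18 other LXR target genes, 6 of them in the lists set beforehand. Their median log2 fold change was 0.114 (SE of the median 0.316) and their mean -0.144, with 9 lower and 9 higher (camera p = 0.632; 0.748 with an estimated correlation). These targets therefore did not show a common fall, but members that go both ways leave the hypothesis open. Bulk liver RNA does not show which cells carried these targets. Their median thus could not decide on LXR activity in the cells that carry Abcg5 and Abcg8.

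Cell cycle genes were called lower with AL/NP at the preset correlation and not with an estimated one (adjusted p = 0.400). Fewer cells in DNA replication rather than in mitosis was tested with genes outside that list. These genes were chosen after the data were seen and measured in the same libraries, so their own fall is no independent support. Their p-values were adjusted over the 3 added lists only and cannot be set beside those of the lists fixed beforehand. Replication genes had a median of -0.566 (31 of 36 lower; camera adjusted p = 3.80e-10; adjusted p = 0.00758 over the 3 added lists with an estimated correlation). Mitosis genes had a median of -0.636 (29 of 31 lower; camera adjusted p = 2.09e-06; adjusted p = 0.226 with an estimated correlation). The difference, 0.0703, was smaller than its standard error of 0.165, and it was -0.218 without control replicate 3, where the mitosis median was -0.361. The test could not separate a replication effect from one on mitosis.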
